A study of Arabidopsis thaliana with 9 samples.

How the data were processed

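Polyadenylated RNA was measured in 9 libraries of whole Arabidopsis thaliana seedlings 6 days old, in 3 groups of 3: Col-0 with a mock solution (ethanol diluted 5000-fold), Col-0 with jasmonate at 5 µM for 3 h, and lhp1 with the mock solution. Per the labels, seedlings grew in liquid MS medium with sucrose, RNA was purified with an RNeasy kit, polyadenylated RNA was selected with NEBNext beads, and NEBNext libraries were sequenced on a NovaSeq instrument. The labels write the dose as 5 µm, read here as micromolar. Their treatment field separates the groups, while their protocol field has the same jasmonate wording for all samples. The labels give the mutant as lhp1, and an allele number stands in the column names alone. The replicate numbers come from the sample titles.

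The authors deposited a table of whole-number read counts per gene for 33602 genes, not normalized, per the values in it. Per the submitters' processing notes the tools were TopHat, HTSeq and edgeR and the build TAIR10, with no versions or settings given. Whether counting used the strand, and how reads with several matches were treated, is not given in the sources used here, so values of near-identical genes (PDF1.2a, PDF1.2b and PDF1.2c, the LHCB1 and RBCS genes, AOC1 and AOC2, VSP1 and VSP2, LTP3 and LTP4) and of overlapping or antisense genes are uncertain. The table held 3 further per-library columns that match no sample in the labels, and they were not used here. Gene names and coordinates came from the RefSeq annotation of TAIR10.1, matched by locus identifier for 32835 of the 33602 genes.

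Counts were analysed as deposited. Library totals ranged from 18081553 to 31454984, the mock lhp1 libraries being the shallowest, and 0.429% to 0.634% of counts fell on organelle genes. The largest gene took 0.634% to 1.71% of a library. Of the 33602 genes 8312 had no count in any of the 9 libraries, and filterByExpr kept 20986. Replicates of each group differed by more than sampling noise: over genes with at least 20 counts in a pair, chi-square per degree of freedom was 37.9, 26.2 and 20.8 between mock WT replicates 1 and 2, 1 and 3, and 2 and 3, 5.70 to 11.9 among JA WT and 2.47 to 3.68 among mock lhp1 libraries. The biological coefficient of variation was 0.106, and 0.0906 without mock WT replicate 2.

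All 9 libraries entered 1 model with a mean per group and no covariate, fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit, glmQLFTest, two-sided, Benjamini-Hochberg adjusted p below 0.05). The contrasts were JA WT minus mock WT, mock lhp1 minus mock WT, and JA WT minus mock lhp1. The value after ± beside a log2 fold change is an approximate standard error. It was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For genes near 0 counts in a group it may not reflect the spread between libraries. Where a group had 0 counts of a gene, its fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with an exact 95% counting interval. These intervals and floors cover counting error and no other variation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

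The groups, tests, gene lists, named genes and alternatives were fixed before the data were examined, apart from those said to be added later. The 23 lists held 298 genes: JAZ repressors, jasmonate biosynthesis, jasmonate catabolism, jasmonate transcription factors and receptor, MYC-branch wound and defence outputs, ERF-branch defence outputs, glucosinolate biosynthesis, tryptophan biosynthesis, flavonoid and anthocyanin biosynthesis, salicylate defence, abscisic acid and dehydration response, YUCCA auxin synthesis, Polycomb components and antagonists, floral organ identity MADS genes, flowering time regulators, meristem and KNOX regulators, seed maturation, photosynthesis antenna and Rubisco small subunit genes, mitotic cell cycle, root hair, root tip and endodermis, stomatal lineage, and circadian clock. The 22 lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry.

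Genes were named by rule. For each comparison with mock WT these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, up to 4 called members per list with the largest change (2 for the marker, clock and cell cycle lists), and, whatever their p, LHP1, VSP2, JAZ10, MYC2, PDF1.2a, FT, FLC, AG and SEP3. For the overlap they were 6 genes each of those higher in both, lower in both and opposite, ranked by the smaller change among those with a mean of at least 5 CPM, and for JA WT against mock lhp1 the 4 largest per direction under the same limits as against mock WT. Members of a list named because they did not pass, called members outside these numbers (NINJA, LDOX and CCA1 after jasmonate, AOC4, KAT2, JAM1, LHCB1.3, CDKB1;1, CASP1, SPCH and FAMA in lhp1), and LTP4, CYP709B1 and AT3G44870's place beside FAMT, were chosen after their values were seen. The values of 1 gene that the rule names are not reported here.

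For the overlap and covariance of the 2 comparisons that share mock WT, 40 simulations of unchanged groups were run. All libraries, mock WT included, were redrawn from 1 mean per gene over the mock WT and JA WT libraries. With no gene changed hardly any is called, so their overlap is no chance level for changed genes. The position of a library between wild type and lhp1 used genes called between JA WT and mock lhp1 in a fit of those 6 libraries alone with an absolute log2 fold change of at least 1, at least 4 CPM in 1 of the groups, and a log2 ratio within 0.5 between mock WT replicates 1 and 3 and JA WT (with 0.5 CPM added).

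The alternatives were DESeq2 1.42.0, limma voom, median-ratio (RLE) factors, total counts, no low-count filter, 1 CPM in at least 3 libraries, the 2 compared groups alone, the replicate number as a block, an absolute log2 fold change of at least 1, a prior count of 0.5 for the list tests, and each of the 9 libraries left out in turn. Repeating gene lists, named genes and overlaps without mock WT replicate 2 was added after seeing the data. The tests were checked on simulated counts for 20986 genes with 200 changed genes per contrast. For jasmonate 53.7%, 88.1% and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered, with 14 false calls among 174. For lhp1 the shares were 59.7%, 83.6% and 98.5%, with 8 false calls among 169. Low-count genes were not among the changed ones, and all means came from mock WT replicates 1 and 3. These rates thus do not cover low-count genes or a deviating library.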

Results

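The series measured polyadenylated RNA from whole Arabidopsis thaliana seedlings 6 days old, and its title places the work in jasmonate signaling, where JAZ proteins repress jasmonate-responsive transcription and Polycomb proteins keep chromatin silent. There were 3 groups of 3 libraries, which the design text calls biological replicates. Wild-type Col-0 seedlings received a mock solution (ethanol diluted 5000-fold; mock WT) or 5 µM jasmonate for 3 h (JA WT), and lhp1 seedlings received the mock solution (mock lhp1). LHP1 is a Polycomb-associated chromodomain protein that binds chromatin carrying histone H3 lysine 27 trimethylation. The total count was 24906304, 26851011 and 26700682 in mock WT replicates 1 to 3, 25613991, 22360776 and 31454984 in JA WT, and 18502265, 18081553 and 20614062 in mock lhp1. Between 22839 and 23392 genes had at least 1 count in a library. CPM values below are counts scaled to library size with TMM factors of 0.911 to 1.1.

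The lhp1 libraries carried less LHP1 RNA. LHP1 (AT5G17690, chromosome 5, 5827142–5829763) stood at 17.8 ± 3.49 CPM in mock WT, 19.1 ± 0.555 in JA WT and 9.43 ± 0.967 in mock lhp1 (mean ± SD, n = 3). Its log2 fold change in lhp1 was −0.91 ± 0.14 (approximate SE derived from the F statistic, edgeR adjusted p = 0.0012), which left 53.2% of the mock WT level. The 3 mock lhp1 libraries, which were shallower, had 207, 165 and 223 counts of the gene, against 495, 385 and 494 in mock WT. Scaled to library size these were 10.2, 8.33 and 9.81 CPM against 20.7, 13.9 and 18.6 CPM, with mock WT replicate 2 the lowest of its group. Without mock WT replicate 2 the change was −1.06 and the remaining level 48.0%. LHP1 after JA differed by 0.11 ± 0.13 (edgeR adjusted p = 0.650), and the sign turned without mock WT replicate 2 (−0.0431) and with total-count scaling (−0.0103).

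Mock WT replicate 2 stood apart from the other mock WT libraries. In a principal component analysis of log2 CPM, component 1 (60.6% of the variance) placed the JA WT libraries between −60.7 and −57.9 and the mock lhp1 libraries between 55.3 and 58.1. The same component placed mock WT replicates 1 to 3 at −9.44, 29.2 and −11.7. The floral gene SEP3 was measured at 27.8, 94.6 and 26.4 CPM in mock WT replicates 1 to 3. In JA WT it was at 21.6 to 26.2 CPM and in mock lhp1 at 156 to 159 CPM. The lipid transfer protein gene LTP4 was measured at 0.0419, 211 and 0.0754 CPM in the mock WT libraries and at 350 to 415 CPM in mock lhp1. Its position was taken over genes that differed between mock lhp1 and JA WT and were alike in JA WT and mock WT replicates 1 and 3. Over 365 genes higher in mock lhp1 the library lay a median of 51.7% of the way from the other mock WT libraries to mock lhp1 (quartiles 45% to 59.0%). Over 320 genes lower in mock lhp1 it lay at 48.8% (quartiles 42.2% to 54.3%). The medians were 48.4% and 46.3% with total-count scaling. For mock WT replicates 1 and 3, each placed against the other, the medians were 0.352% and −0.311% over the higher genes and −24.3% and 21.1% over the lower genes. For the JA WT libraries they lay between −4.07% and 4.44%. The library stayed in all tests, as its label puts it in mock WT, and values without it are given beside results that move with it. It was singled out after its values were seen to lie toward mock lhp1. Leaving it out thus widens, by construction, the lhp1 changes of genes where it lay between the groups. The p-values without it rest on mock WT replicates 1 and 3 and are descriptive.

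**Figure D1:**
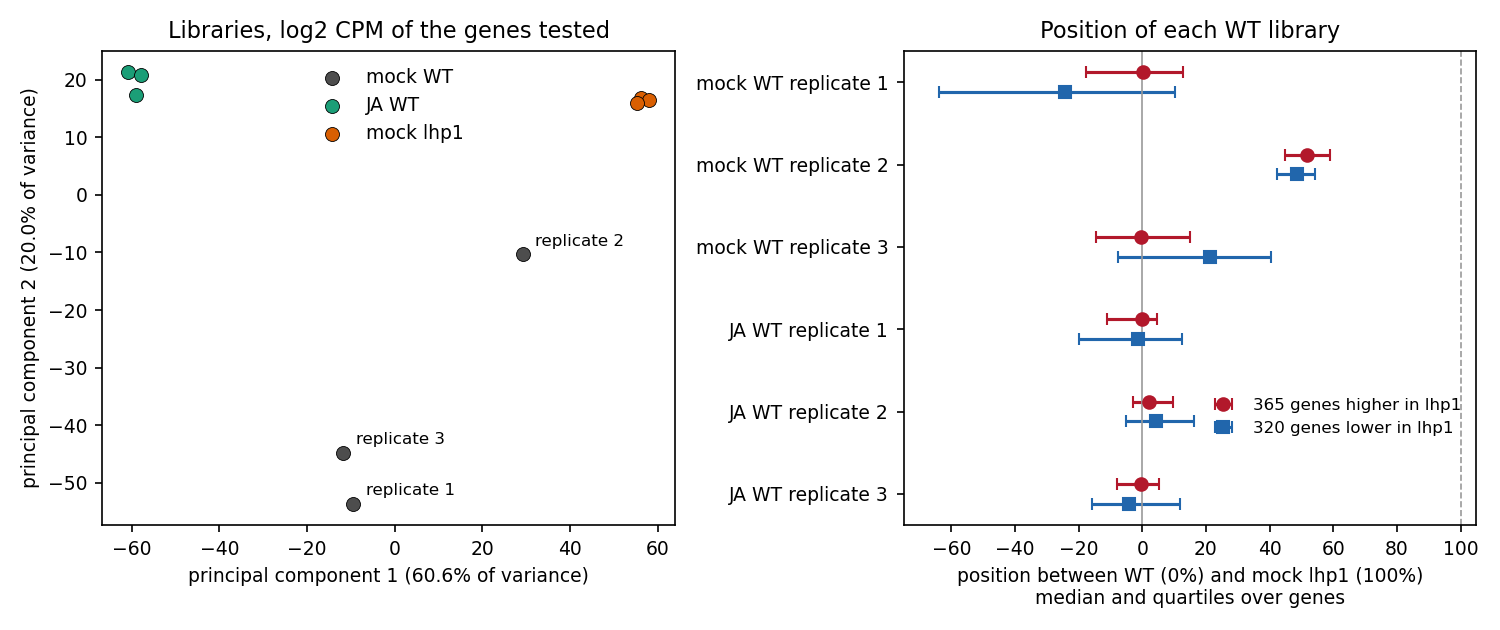
Left, the 9 libraries (points, coloured by group) on the first 2 principal components of log2 CPM; right, for each wild-type library, the median position (points; bars, quartiles over genes) between the other libraries of its group (0%) and mock lhp1 (100%), for 365 genes higher and 320 genes lower in lhp1. Mock WT replicate 2 sits at 51.7% and 48.8%, and the JA WT libraries lie between −4.07% and 4.44%.

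Jasmonate for 3 h raised the genes that encode its own repressors, synthesis and breakdown. JAZ10 (AT5G13220, chromosome 5, 4218786–4221077), whose product represses MYC transcription factors, rose from 2.91 ± 0.303 to 104 ± 3.14 CPM (mean ± SD, n = 3; log2 fold change 5.16 ± 0.10, edgeR adjusted p = 4.62e-10). FAMT (AT3G44860, chromosome 3, 16379571–16381434), a farnesoic acid methyltransferase gene, had the largest rise among the genes named by size, from 0.367 ± 0.532 to 120 ± 39.8 CPM (log2 fold change 8.32 ± 0.47, edgeR adjusted p = 3.28e-07), and its neighbour AT3G44870 rose by 7.52 ± 0.26 on the log2 scale. The tyrosine aminotransferase gene TAT3 (7.27 ± 0.29), the jasmonate oxidase genes JOX3 (7.19 ± 0.29) and JOX4 (6.97 ± 0.27) and AT5G04120 (6.34 ± 0.24) completed the 6 largest rises. VSP2 (AT5G24770, chromosome 5, 8500468–8502224), a vegetative storage protein gene and a classical jasmonate marker, rose from 0.918 ± 0.933 to 53.5 ± 6.01 CPM (log2 fold change 5.82 ± 0.38, edgeR adjusted p = 1.04e-06), and by 7.13 without mock WT replicate 2.

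In total, 1809 genes were higher and 1483 lower after jasmonate among 20986 tested (15.7%; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), and 646 and 415 of them changed at least 2-fold. Without mock WT replicate 2 the counts were 1743 and 1328, with 1533 and 1127 genes called both ways. They were 1843 and 1998 without mock WT replicate 3, where lower genes outnumbered higher ones. In 30.1% of the tested genes the 3 JA WT values did not overlap the 3 mock WT values, where chance gives 10%. Scaling by total counts shifted all log2 fold changes by a median of −0.12 and gave 1217 higher and 3034 lower genes, and 934 were lower with only the 2 compared groups in the fit. The share of calls that were higher moved from 55.0% to 28.6%, and changes below are on the TMM scale.

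All 9 measured jasmonate catabolism genes were higher, as were 11 of 13 JAZ genes, 13 of 15 biosynthesis genes (12 in every fit without 1 library) and all 6 measured MYC-branch outputs. Adjusted over the list alone, 9, 11, 13 and 6 were higher and 1 biosynthesis gene was lower. Among the JAZ genes, JAZ8 rose by 5.95, JAZ13 by 4.44 and JAZ9 by 4.12 ± 0.12 on the log2 scale. JAZ4 (0.16, edgeR adjusted p = 0.628) and JAZ11 (0.21, edgeR adjusted p = 0.178) did not pass. In biosynthesis, AOC1 rose by 4.36 ± 0.15, LOX2 by 3.92 ± 0.35 and AOS by 3.74 ± 0.19. AOC2 rose from 37.9 ± 12 to 485 ± 57.3 CPM (3.68 ± 0.20). The conjugating enzyme gene JAR1 (−0.15) and the β-oxidation gene KAT2 (0.03) did not pass. Of the catabolism genes, the oxidases CYP94B1 (4.28 ± 0.13) and JOX2 (3.80 ± 0.13) and the sulfotransferase ST2A (2.23) rose. In the MYC branch, CLH1 rose by 4.56 ± 0.14, VSP1 by 3.65 ± 0.42, and CORI3 by 2.45 ± 0.49 (3.40 without mock WT replicate 2). The terpene synthase gene TPS04 had 104 counts in JA WT and 3 in mock WT, a ratio of 37.3 (12.4 to 184). Without mock WT replicate 2 the ratio was 24.1 (8.01 to 119). The list medians were 3.42 for JAZ, 1.46 for biosynthesis (1.91 without mock WT replicate 2), 3.49 for catabolism and 4.81 for the MYC branch. The camera adjusted p-values were 2.64e-17, 1.61e-13, 1.35e-14 and 8.94e-09, and the adjusted p with an estimated correlation was 0.00805, 0.00588, 0.00805 and 0.0138.

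Of 14 measured jasmonate transcription factors and receptor components, 9 rose (9 adjusted over the list alone), 5 of them in every fit that left out 1 library. MYC2 (AT1G32640, chromosome 1, 11798119–11801407), the central jasmonate activator, rose from 29.0 ± 5.68 to 128 ± 4.05 CPM (2.15 ± 0.12, edgeR adjusted p = 3.34e-07). ANAC019 rose by 2.75 ± 0.26, RGL3 by 1.77 ± 0.21 and the co-repressor adaptor NINJA by 0.84. The receptor gene COI1 (−0.12, edgeR adjusted p = 0.249) and MYC4 (−0.20, edgeR adjusted p = 0.234) did not pass. BHLH14 was measured at 0.126, 3.00 and 0.113 CPM in mock WT, with a log2 fold change of −1.83 (edgeR adjusted p = 0.27) that turned to 1.33 without mock WT replicate 2. ANAC055 rose by 2.09, a call lost without JA WT replicate 3 (edgeR adjusted p = 0.0700). The list median was 0.53 (camera adjusted p = 5.37e-05, adjusted p = 0.0698 with an estimated correlation, and 0.0261 without mock WT replicate 2, where the median was 0.83 and 8 rose).

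Of 8 ERF-branch defence outputs 5 rose, also adjusted over the list alone, with a median of 1.75 (camera adjusted p = 0.000325, adjusted p = 0.168 with an estimated correlation). ERF1 rose by 3.12 ± 0.39 and ORA59 by 1.4 ± 0.09. The defensin genes PDF1.2b and PDF1.2c, at 9 and 11 counts in mock WT, rose by 3.49 ± 0.62 and 3.19 ± 0.70 (4.88 for PDF1.2c without mock WT replicate 2). The defensin gene PDF1.2a went from 0.624 ± 0.336 to 2.75 ± 0.534 CPM (2.11 ± 0.45, edgeR adjusted p = 0.00849). PR3 (−0.11), PR4 (0.47) and PDF1.3 (0.59) did not pass.

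Genes in 3 lists of defence compound metabolism rose. In glucosinolate biosynthesis 20 of 24 genes rose (20 adjusted over the list alone, 18 in every fit without 1 library; median 0.93, camera adjusted p = 1.09e-16, adjusted p = 0.0366 with an estimated correlation). Among them the indole branch gene CYP79B2 went from 152 to 669 CPM (2.13 ± 0.08), and CYP79B3 (1.94), CYP83B1 (1.75) and IGMT1 (2.22 ± 0.20) rose too. MYB51 (−0.28), MYB28 (0.03), MAM3 (0.10) and CYP81F2 (0.31) did not pass. All 7 tryptophan biosynthesis genes rose (7 adjusted over the list alone; median 1.44, camera adjusted p = 1.44e-11, adjusted p = 0.0138 with an estimated correlation). They included ASA1 (1.69 ± 0.06), TSA1 (1.71 ± 0.13), IGPS (1.57 ± 0.08) and ASB1 (1.44 ± 0.09), which act on the way to indole glucosinolates. In flavonoid and anthocyanin biosynthesis 9 of 17 genes rose, 7 of them in every fit without 1 library, and 10 rose and 1 fell adjusted over the list alone. DFR rose by 2.85 ± 0.17, LDOX by 2.69, UGT79B1 by 2.84 and the anthocyanin activator PAP1 by 3.30 ± 0.41. CHS, which acts at the first step, differed by 0.24 (edgeR adjusted p = 0.174) and the repressor gene MYBL2 by −0.78 (edgeR adjusted p = 0.053). MYB113 had 73 counts in JA WT and 0 in mock WT, at least 26.2-fold higher, or at least 16.9-fold without mock WT replicate 2. The flavonoid median of 0.41 was the same with that gene at its bound (camera adjusted p = 5.90e-06, adjusted p = 0.118 with an estimated correlation).

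The nitrate transporter gene NRT2.1 (AT1G08090, chromosome 1, 2524023–2526322) fell from 17.0 ± 6.25 to 0.689 ± 0.273 CPM after jasmonate (log2 fold change −4.66 ± 0.32, edgeR adjusted p = 1.86e-06). GSTF14 fell from 53.6 ± 19.9 to 6.33 ± 1.18 CPM (−3.09 ± 0.25), and PP2-A3 (−2.88 ± 0.23) and AT5G59680 (−2.66 ± 0.20) fell too. The other 2 of the 6 largest falls moved with mock WT replicate 2. LTP3, measured at 1.55, 192 and 1.96 CPM in mock WT, differed by −5.84 ± 1.66 (edgeR adjusted p = 0.0346) and by −0.63 without that library (edgeR adjusted p = 0.0557). AT5G47330 fell (−2.91, edgeR adjusted p = 0.040; −0.98 without it), a call lost without any 1 of the JA WT or mock lhp1 libraries.

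Floral organ identity genes were called lower as a list after jasmonate, with values that rested on mock WT replicate 2. The median over 10 measured genes was −2.79 (2 lower over all genes, 7 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.607 with an estimated correlation). Without mock WT replicate 2 the median over 11 measured genes was −0.25 and the mean 0.16 (camera adjusted p = 0.196), and without JA WT replicate 2 the camera adjusted p was 0.0522. AG was measured at 0.837, 5.67 and 1.09 CPM in mock WT and at 0.294 to 0.415 CPM in JA WT (−2.78 ± 0.72, edgeR adjusted p = 0.0232; −1.37 without mock WT replicate 2), a call lost without any 1 JA WT library. SEP4 fell (−0.63 ± 0.15, edgeR adjusted p = 0.0126), and SEP3 differed by −1.08 (edgeR adjusted p = 0.0926; −0.20 without mock WT replicate 2). None of 10 flowering time regulators passed in edgeR's test (median −0.25, camera adjusted p = 0.326; −0.05 and 0.882 without mock WT replicate 2), where 2 had an unadjusted edgeR p under 0.05, DESeq2 called 2 and voom 0. FT, the mobile flowering signal, had 63 counts in mock WT and 0 in JA WT, at least 19.5-fold lower (edgeR adjusted p = 0.0886). The mock WT libraries had 0.126, 2.17 and 0 CPM of it, and FLC differed by −0.27 (edgeR adjusted p = 0.558).

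The meristem and KNOX list was called lower by camera after jasmonate (median −0.48; 2 of 7 lower, 2 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.108 with an estimated correlation; 1 lower and 0.0270 by camera without mock WT replicate 2). KNAT1 fell (−0.49, edgeR adjusted p = 0.0314, lost without JA WT replicate 3, mock WT replicate 1 or any mock lhp1 library). STM fell (−0.64, edgeR adjusted p = 0.0354, lost without JA WT replicates 2 or 3, mock WT replicates 1 or 2, or mock lhp1 replicate 3). Of 12 clock genes 3 fell, also adjusted over the list alone (median −0.16, camera adjusted p = 0.0795). They were CCA1 (−0.38, edgeR adjusted p = 0.012), ELF4 (−0.94, lost without JA WT replicates 2 or 3 or mock WT replicate 2) and PRR9 (−0.39, lost without JA WT replicate 2). The fry test, which asks whether the genes of a set move on balance in 1 direction and does not compare the set with other genes or sets, gave the clock list an adjusted p of 0.00283 and the meristem list 0.00329.

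The other lists were not called after jasmonate. Of 13 salicylate defence genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; median 0.20, camera adjusted p = 0.938). Without mock WT replicate 2 the median was 0.04, with 1 higher and 1 lower. The 3 genes were EDS5 (1.78 ± 0.16), EDS1 (−0.34, edgeR adjusted p = 0.00419) and FMO1 (−0.87, lost without JA WT replicates 2 or 3 or mock WT replicates 1 or 2). Of 11 abscisic acid and dehydration genes 2 fell, also adjusted over the list alone (median −0.40, camera adjusted p = 0.0746, and 0.00277 without mock WT replicate 3). Leaving out mock WT replicate 2 gave −0.26 and 0.365, with 1 higher and 1 lower. The 2 genes were COR47 (329 to 168 CPM, −0.97 ± 0.14) and the phosphatase gene HAB1 (−0.35, lost without JA WT replicates 1 or 2 or mock WT replicate 2), whose product restrains abscisic acid signaling. Of 7 YUCCA auxin synthesis genes YUC6 fell (−0.73 ± 0.14), and adjusted over the list alone 1 rose and 1 fell (median 0.15, and −0.06 without mock WT replicate 2, camera adjusted p = 0.895). Of 18 Polycomb components and antagonists 1 fell, also adjusted over the list alone, SWN (41.6 to 34.7 CPM; −0.26 ± 0.06, edgeR adjusted p = 0.0097). Their median was 0.01, their mean −0.09 and the camera direction down (adjusted p = 0.938), and the median turned to −0.12 with total counts. Of the 2 measured seed maturation genes, too few for a set test, SESA1 rose (1 adjusted over the list alone). It had 48 counts against 2, a ratio of 25.8 with a 95% counting interval of 6.77 to 219. Without mock WT replicate 2 the ratio was 16.7 (4.37 to 142), and 1 of 5 genes rose (camera adjusted p = 0.413).

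Among the markers of organs and cell types 1 gene was called after jasmonate. In edgeR's test no gene passed among 18 photosynthesis genes (median 0.06, −0.05 with total counts and −0.12 without mock WT replicate 2, camera adjusted p = 0.326, and 9.72e-06 without mock WT replicate 1), 18 cell cycle genes (median −0.06, camera adjusted p = 0.367, and 0.0283 without mock WT replicate 1; median −0.0018 without mock WT replicate 2), 7 root hair genes (median 0.01, 0.08 without mock WT replicate 2, mean −0.03, −0.11 with total counts, camera adjusted p = 0.938) and 8 stomatal lineage genes (median 0.08, −0.04 with total counts, camera adjusted p = 0.612), nor adjusted over the list alone. At an unadjusted edgeR p under 0.05 there were 0, 2, 0 and 1 genes, DESeq2 called 0, 0, 0 and 0, and voom called 0, 0, 0 and 1. Of 10 root tip and endodermis genes CASP5 fell (−1.92, edgeR adjusted p = 0.0496; lost in 8 of the 9 fits without 1 library; 0 adjusted over the list alone; median −0.10, camera adjusted p = 0.580; 0 called and a median of 0.0024 without mock WT replicate 2). In all, 11 of 22 lists were called, 10 without mock WT replicate 2 and 6 with an estimated correlation (JAZ, biosynthesis, catabolism, MYC branch, glucosinolate and tryptophan).

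**Figure D2:**
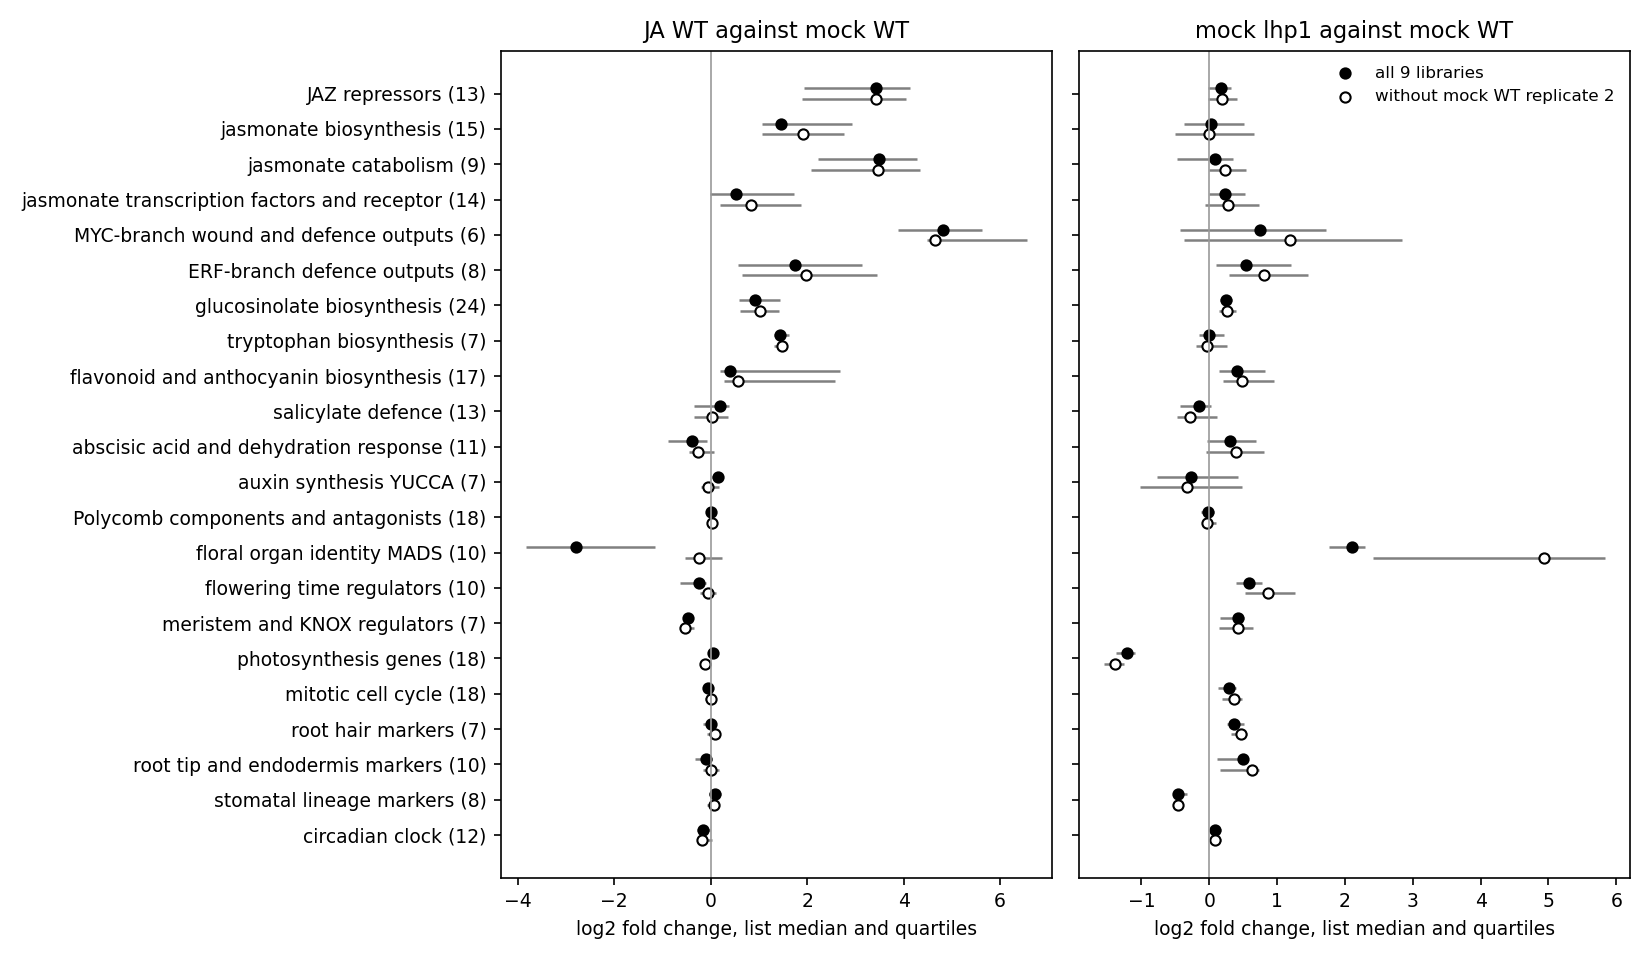
Median log2 fold change against mock WT (points; bars, quartiles over the measured genes) of the 22 tested gene lists after jasmonate and in lhp1, filled with all 9 libraries and open without mock WT replicate 2. The JAZ median is 3.42 after jasmonate, the photosynthesis median −1.22 in lhp1, and the floral median in lhp1 moves from 2.11 to 4.94 without that library; the photosynthesis, stomatal, Polycomb and root hair medians after jasmonate (0.06, 0.08, 0.01 and 0.01) and the Polycomb median in lhp1 (−0.02) turn sign with total counts.

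In lhp1 seedlings all 18 measured antenna and Rubisco small subunit genes, whose products capture light and fix carbon, were lower than in mock WT (18 adjusted over the list alone, and in every fit that left out 1 library). LHCB1.4 (AT2G34430, chromosome 2, 14524607–14525918) fell from 1753 ± 967 to 266 ± 8.19 CPM (mean ± SD, n = 3; log2 fold change −2.72 ± 0.31, edgeR adjusted p = 0.00027). RBCS2B fell from 1833 ± 412 to 570 ± 13.6 CPM (−1.68 ± 0.14), and LHCB1.3 fell as well (−1.11). The list median was −1.22 (camera adjusted p = 4.53e-14, adjusted p = 0.482 with an estimated correlation), −1.38 without mock WT replicate 2 and −1.06 with total counts. These genes took 6.65 ± 1.43% of all counts in mock WT (8.19%, 5.37% and 6.37% in replicates 1 to 3), 6.58 ± 0.173% in JA WT and 3.25 ± 0.0455% in mock lhp1. In the same comparison the median was −0.46 for stomatal lineage markers, 0.50 for root tip and endodermis markers and 0.36 for root hair markers.

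Of 10 measured floral organ identity genes 6 were called higher in lhp1, 2 of them in every fit without 1 library, and the list call was lost with an estimated correlation (camera adjusted p = 0.000129, adjusted p = 0.482 with an estimated correlation). SEP3 (chromosome 1, 8593536–8596123) went from 49.6 ± 39.0 to 158 ± 1.42 CPM (log2 fold change 1.66 ± 0.38, edgeR adjusted p = 0.00992) and AG (AT4G18960, chromosome 4, 10382856–10388539) from 2.53 ± 2.72 to 11.3 ± 0.629 CPM (2.14 ± 0.50, edgeR adjusted p = 0.0103). Mock WT replicate 2 lay between the groups for these genes, and without it the changes were 2.54 and 3.54. AP3, at 0.544, 16.4 and 0.415 CPM in mock WT and 28.8 to 30.2 CPM in mock lhp1, differed by 2.31 (edgeR adjusted p = 0.0561) with all libraries and rose by 5.93 without that library (edgeR adjusted p = 3.50e-09). PI differed by 2.06 (edgeR adjusted p = 0.0572) and rose by 4.94 without it. SEP1 rose by 2.55 (6.22 without mock WT replicate 2, lost without mock WT replicate 3 or any mock lhp1 library). SEP2 had 214 counts in mock lhp1 and 0 in mock WT replicates 1 and 3, at least 57.1-fold higher, and STK 150 against 2, a ratio of 60.1 (16.3 to 500). With all libraries STK rose by 2.55 (lost in 4 of the 9 fits without 1 library) and SHP2 by 2.25 (5.34 without mock WT replicate 2, lost in the 8 other such fits). SEP4 differed by 0.32 (edgeR adjusted p = 0.111). The list median was 2.11, and 10 genes passed adjusted over the list alone. Leaving out mock WT replicate 2 gave 9 of 11 higher, with a median of 4.94 that was the same with genes at 0 counts set to their bound (camera adjusted p = 2.93e-10, adjusted p = 0.0738 with an estimated correlation).

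The largest falls in lhp1 held in every fit without 1 library. MRD1 (AT1G53480, chromosome 1, 19963047–19964712) fell from 29.2 ± 10.8 to 0.256 ± 0.207 CPM (−6.81 ± 0.43, edgeR adjusted p = 9.08e-05). AT5G44440 fell (−4.83 ± 0.62), as did CYP706A6 from 28.6 to 3.08 CPM (−3.21 ± 0.28), AT5G57760 (−2.93), the bHLH gene HEC1 from 14.8 to 2.06 CPM (−2.85 ± 0.23) and AT5G02760 from 158 to 22.1 CPM (−2.84 ± 0.19). The largest rises moved with mock WT replicate 2: besides SEP1 they were AT2G16005 (2.53; 5.50 without it), AT5G39220 (2.45; 5.37), the exocyst gene EXO70H8 (2.35; 4.78), the retroposon SADHU5-1 (2.34; 4.46) and AT1G11070 (2.33; 4.66). Each of these calls was lost without any 1 mock lhp1 library. Calls of AT2G16005, AT5G39220 and AT1G11070 were also lost without mock WT replicate 3, the call of AT5G39220 without JA WT replicate 2 and that of AT1G11070 without any 1 JA WT library. CYP709B1 had 0, 22.6 and 0 CPM in mock WT and up to 41.2 CPM in mock lhp1 (2.39, edgeR adjusted p = 0.0963), at least 680-fold higher without mock WT replicate 2. LTP4 differed by 2.47 (edgeR adjusted p = 0.203), and had 24665 counts in mock lhp1 against 3 in mock WT replicates 1 and 3, a ratio of 6583 (95% counting interval 2252 to 31924).

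In total, 2321 genes were higher and 3023 lower in lhp1 among 20986 tested (25.5%; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05), 387 and 478 of them at least 2-fold. Without mock WT replicate 2 the counts were 3295 and 3571 (843 and 685 at least 2-fold), with 2247 and 2959 genes called both ways. The higher count was 1364 without mock WT replicate 3 and 1215, 1108 and 1340 without mock lhp1 replicates 1, 2 and 3. Values of the groups did not overlap in 44.6% of genes, where chance gives 10%. Total-count scaling shifted log2 fold changes by a median of 0.15 and gave 5045 higher and 1878 lower genes. The share that was higher moved from 43.4% to 72.9%.

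Jasmonate genes moved in both directions in lhp1 without jasmonate. The synthesis gene AOC2 (AT3G25770, chromosome 3, 9406669–9408071) fell from 37.9 ± 12 to 7.15 ± 0.776 CPM (−2.40 ± 0.21, edgeR adjusted p = 0.000122), AOC1 fell (−1.42 ± 0.17) and AOS (−0.81 ± 0.18). In contrast, AOC3 (0.92 ± 0.15), AOC4 (0.51) and KAT2 (0.52) rose. Of 15 biosynthesis genes 3 rose and 4 fell, also adjusted over the list alone (median 0.03, mean −0.14, camera direction down with adjusted p = 0.781; median 0.0028 without mock WT replicate 2). Of 9 catabolism genes IAR3 rose (0.51) and 2 fell, ST2A from 17.1 to 4.1 CPM (−2.05 ± 0.29) and ILL6 (−0.48, lost without mock WT replicate 1 or mock lhp1 replicates 1 or 3). Adjusted over the list alone 2 were higher and 2 lower (median 0.08, mean −0.18; camera direction up, fry direction down, camera adjusted p = 0.866). With mock WT replicate 2 left out 3 rose and 2 fell (median 0.24, mean 0.03). VSP2 rose from 0.918 ± 0.933 to 3.83 ± 1.06 CPM (2.02 ± 0.45, edgeR adjusted p = 0.00868; 3.32 without mock WT replicate 2) and VSP1 by 1.73 ± 0.44 (2.89 without it). CORI3 rose by 1.71 (2.66 without it, lost without mock WT replicate 3 or any mock lhp1 library). In all, 3 of 6 MYC-branch outputs rose, also adjusted over the list alone (median 0.75, camera adjusted p = 0.334; 1.18 and 0.118 without mock WT replicate 2). Of 13 JAZ genes JAZ3 rose (0.53 ± 0.09; 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.124; 2 rose without mock WT replicate 2), and JAZ10 differed by 0.16 (edgeR adjusted p = 0.393).

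Of 14 jasmonate transcription factors and receptor components 5 rose, none of them in every fit without 1 library, and JAM1 fell (−0.48, edgeR adjusted p = 0.0089). Adjusted over the list alone 8 rose and 1 fell (median 0.24, camera adjusted p = 0.0835; fry adjusted p = 0.0374). Over all genes 8 rose without mock WT replicate 2 (camera adjusted p = 0.0524). MYC2 differed by 0.33 ± 0.12 (edgeR adjusted p = 0.0668), and rose by 0.44 without mock WT replicate 2 (edgeR adjusted p = 0.0131). BHLH14 rose by 2.25 with all libraries and 5.41 without mock WT replicate 2, a call lost without any 1 of the other 8 libraries. ANAC055 rose by 1.91 (2.94 without mock WT replicate 2), ANAC019 by 0.85 and ANAC072 by 0.54, calls lost in 3, 7 and 6 of the 9 fits without 1 library. Of 8 ERF-branch outputs 2 rose, 4 adjusted over the list alone (median 0.55, camera adjusted p = 0.112, and 0.0299 without mock lhp1 replicate 2; 4 rose, with a median of 0.81, without mock WT replicate 2), among them the chitinase gene PR3, from 28.1 to 60.1 CPM (1.09 ± 0.18), and ORA59 (0.32, lost in 5 of the 9 fits without 1 library). PDF1.2a differed by 0.22 (edgeR adjusted p = 0.788).

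Further lists were called higher in lhp1 by camera, and none with an estimated correlation. Of 24 glucosinolate genes 9 rose (12 adjusted over the list alone; 4 in every fit without 1 library; median 0.24, camera adjusted p = 0.000694, adjusted p = 0.482 with an estimated correlation). They included BCAT4 (0.66 ± 0.11), MAM3 (0.64) and MAM1 (0.61) of methionine chain elongation and SOT18 (0.42 ± 0.07), and 12 rose without mock WT replicate 2. Of 17 flavonoid genes 8 rose (9 adjusted over the list alone, 4 in every fit without 1 library; median 0.40, camera adjusted p = 0.00178, adjusted p = 0.482 with an estimated correlation), with DFR (0.97), LDOX (0.97), F3H (0.77) and F3PH (0.85, lost without mock lhp1 replicate 1). Of 18 cell cycle genes 5 rose (10 adjusted over the list alone, 2 in every fit without 1 library; 8 over all genes without mock WT replicate 2; median 0.29, camera adjusted p = 0.00514, adjusted p = 0.513 with an estimated correlation). CYCB1;4 (0.52), CDKB1;1 (0.45) and CYCB2;3 (0.50, lost in 7 of the 9 fits without 1 library) were among them. Of 10 flowering time regulators 2 rose and 1 fell, also adjusted over the list alone (median 0.58, camera adjusted p = 0.0459, adjusted p = 0.482 with an estimated correlation). In this list 6 rose without mock WT replicate 2 (median 0.86, camera adjusted p = 0.00698). AGL24, a promoter of flowering, rose by 1.54 (2.38 without mock WT replicate 2, lost without mock lhp1 replicate 1) and SVP, a repressor, fell (−0.78 ± 0.12). AGL17 rose by 0.78 (lost in 3 of the 9 fits without 1 library). FT differed by 2.29 (edgeR adjusted p = 0.0795), and had 245 counts against 3 in mock WT replicates 1 and 3, a ratio of 65.4 (22.1 to 319). FLC differed by 0.56 (edgeR adjusted p = 0.132).

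Of 10 root tip and endodermis markers 3 rose, among them CASP1 (0.50) and CASP2 (0.55), and none of the 3 did so in every fit without 1 library. The calls of CASP1 and CASP2 were lost without mock WT replicate 3, any JA WT library or any mock lhp1 library, and that of CASP2 also without mock WT replicate 1. The list was called (4 adjusted over the list alone; 4 over all genes without mock WT replicate 2; median 0.50, camera adjusted p = 0.0459, adjusted p = 0.482 with an estimated correlation). The camera calls of this list and of the flowering list were lost without JA WT replicate 1, 2 or 3 (adjusted p = 0.0597, 0.0549 and 0.0650 for both). The root tip call was also lost without mock WT replicate 1 (0.0777) or mock lhp1 replicate 3 (0.0666), and the flowering call without mock WT replicate 3 (0.0857) or mock lhp1 replicate 3 (0.0705). The stomatal lineage list was called lower by camera (4 of 8 fell, 6 adjusted over the list alone, and 6 without mock WT replicate 2; median −0.46, camera adjusted p = 0.00514, adjusted p = 0.482 with an estimated correlation). Among them were FAMA (−0.44, edgeR adjusted p = 0.00362) and SPCH (−0.48, lost without mock lhp1 replicate 2), BASL (−0.53, lost without mock lhp1 replicate 3) and EPF2 (−0.49, lost in 7 of the 9 fits without 1 library).

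The remaining lists were not called in lhp1. Of 11 abscisic acid genes 4 rose, also adjusted over the list alone (median 0.31, camera adjusted p = 0.0526, 0.0119 without mock WT replicate 1 and 0.0155 without mock WT replicate 2), and 2 of them, COR47 (0.59) and the negative regulator HAB1 (0.44), did so in every fit without 1 library. COR15A rose by 2.19 (4.17 without mock WT replicate 2, lost without any 1 mock lhp1 library). ABI5 rose by 0.78, a call lost in 8 of the 9 such fits, among them the fit without mock WT replicate 2 (0.81, edgeR adjusted p = 0.0624). Of 7 root hair genes 2 rose, also adjusted over the list alone (median 0.36, camera adjusted p = 0.0884, and 0.0300 without mock WT replicate 1). They were COBL9 (0.58) and EXP18 (0.58), lost in 2 and 7 of the 9 fits without 1 library. Of 7 YUCCA genes 1 rose and 2 fell, also adjusted over the list alone (median −0.27, camera adjusted p = 0.721; 3 fell without mock WT replicate 2), with YUC8 at −1.35 ± 0.21. The calls of YUC5 (−0.71) and YUC6 (0.43) were lost in 8 and 4 of the 9 fits without 1 library. Of 18 Polycomb genes EMF1 rose (0.52, lost without mock lhp1 replicate 2) and LHP1 fell, also adjusted over the list alone (median −0.02, mean 0.02, camera direction down with adjusted p = 0.781; the median turned to 0.13 with total counts; 2 rose without mock WT replicate 2). Of 13 salicylate genes 2 rose and 1 fell, also adjusted over the list alone (median −0.15, −0.28 without mock WT replicate 2, camera adjusted p = 0.839). They were PR5 (0.69), EDS5 (0.55) and ICS1 (−0.27), lost in 4, 4 and 7 of the 9 fits without 1 library. Of 7 tryptophan genes 2 rose, also adjusted over the list alone, with TSB2 at 0.41 and ASB1 at 0.26, lost in 6 of the 9 fits without 1 library (median 0.00025 and mean 0.05, with a median of −0.03 without mock WT replicate 2, camera adjusted p = 0.753). Of 7 meristem genes KNAT6 rose (0.47, lost without JA WT replicates 2 or 3, mock WT replicate 3 or mock lhp1 replicates 1 or 2; 0 adjusted over the list alone; median 0.43, camera adjusted p = 0.112). Of 12 clock genes GI rose (0.21, lost in 6 of the 9 fits without 1 library) and PRR7 fell (−0.41), also adjusted over the list alone (median 0.08, camera adjusted p = 0.342; 2 rose without mock WT replicate 2). None of 2 seed maturation genes passed, with 0 at an unadjusted edgeR p under 0.05 and 0 by DESeq2 or voom, and 3 of 5 rose without mock WT replicate 2 (median 2.13, camera adjusted p = 0.118). The list had enough measured members in most fits without 1 library, and was called without mock WT replicate 3 (camera adjusted p = 0.0420) and without mock lhp1 replicate 1 (0.00568). In all, 8 lists were called, 9 without mock WT replicate 2 and 9 with the filter of 1 CPM in at least 3 libraries. There were 7 by fry and 0 by camera with an estimated correlation, where 1 had an unadjusted p under 0.05.

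**Figure D3:**
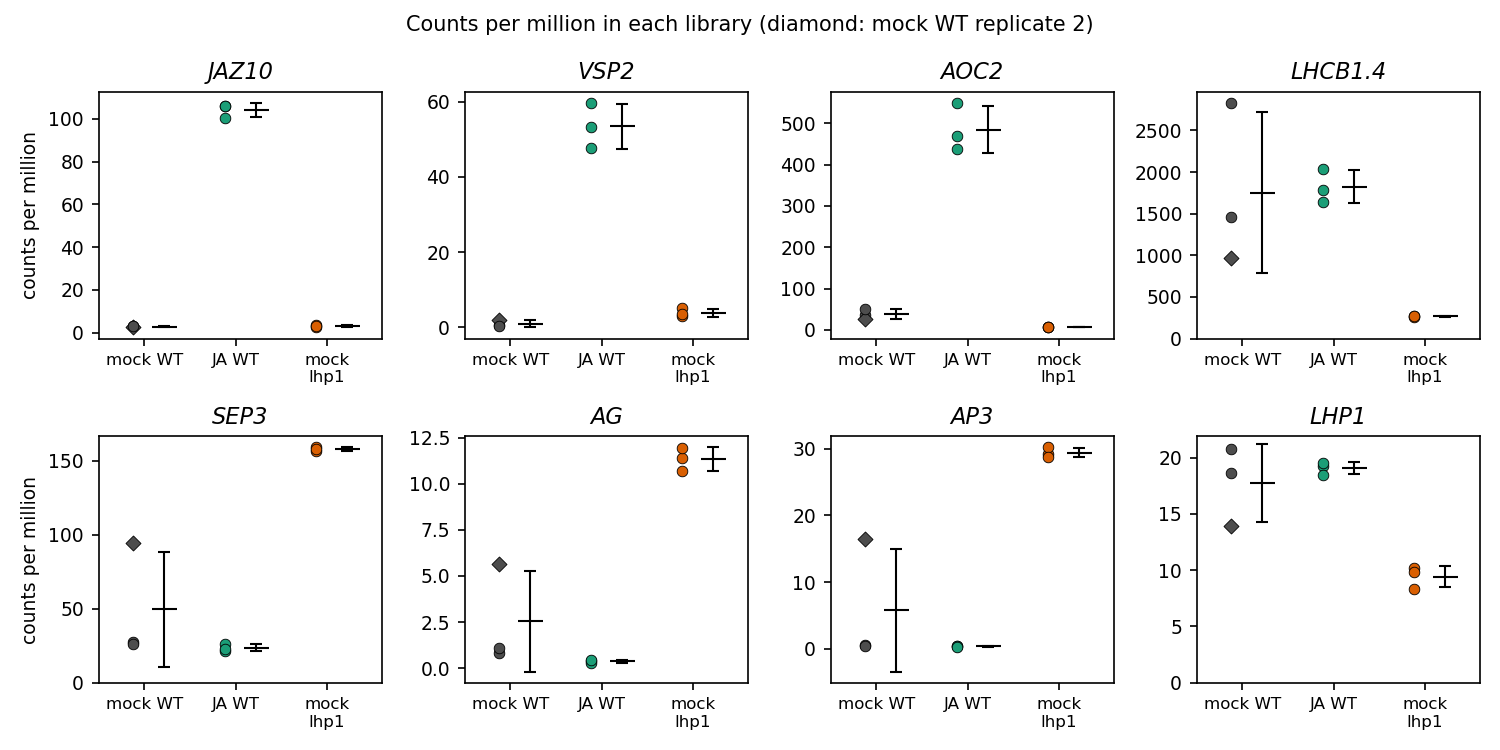
CPM on a linear axis of JAZ10, VSP2, AOC2, LHCB1.4, SEP3, AG, AP3 and LHP1 in mock WT, JA WT and mock lhp1 (dots, libraries; diamond, mock WT replicate 2; bars, mean ± SD, n = 3). JAZ10 goes from 2.91 to 104 CPM after jasmonate, LHCB1.4 from 1753 to 266 CPM in lhp1, and SEP3 in mock WT replicate 2 (94.6 CPM) lies between the other mock WT libraries and mock lhp1.

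Setting JA WT against mock lhp1, which compares the jasmonate and lhp1 states without the mock WT libraries in the contrast, gave 5270 genes higher in JA WT and 4259 higher in mock lhp1 (9529, or 45.4% of tested genes; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). FAMT (9.04 ± 0.52, edgeR adjusted p = 4.41e-07), JOX4 (7.99), TAT3 (7.77) and MRD1 (7.17 ± 0.43) were most in excess in JA WT among called genes with a mean of at least 5 CPM and no overlap between the groups. Under the same limits LTP4 (−12.12, edgeR adjusted p = 0.00357), CYP709B1, LTP3 (−8.30) and SEP1 (−6.59 ± 1.19) were most in excess in mock lhp1. CYP709B1 had 1 count in JA WT and 2548 in mock lhp1, a ratio of 2939 (95% counting interval 527 to 116119). All 18 photosynthesis genes were higher in JA WT (median 1.27, camera adjusted p = 3.97e-09) and all 10 floral genes lower (median −4.99, camera adjusted p = 1.59e-05). Also higher were 11 JAZ (median 2.96), 9 catabolism (median 3.44) and 7 tryptophan genes (median 1.36), and 7 of 11 abscisic acid genes were lower (median −0.71, camera adjusted p = 0.00723). Of 14 lists called, biosynthesis and catabolism held with an estimated correlation (adjusted p = 0.0462 with an estimated correlation for both). With mock WT replicate 2 left out, biosynthesis was lost (0.0962) and the floral list gained (adjusted p = 0.0442 with an estimated correlation, as for catabolism). Total-count scaling shifted these changes by a median of −0.24 and moved the share higher in JA WT from 55.3% to 21.4%.

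Both comparisons against mock WT share its 3 libraries. Simulated groups with no gene changed, where hardly any gene is called, gave a mean of 0.05 higher in both. That value is no chance level for changed genes. In the data 436 genes were higher in both, where independent lists would give 200. They included VSP2 (5.82 after jasmonate, 2.02 in lhp1), AT5G04120 (6.34 and 2.05), VSP1 (3.65 and 1.73), JAL23 (5.04 and 2.07; the lhp1 call was lost without mock lhp1 replicate 2), CORI3 (2.45 and 1.71) and AT1G77520 (1.89 and 1.64). Lower in both were 156 genes (214 for independent lists), among them ORP4C (−1.98 and −2.58), GASA6 (−1.98 and −2.62), FRO6 (−1.57 and −1.23), FBA5 (−1.45 and −2.39), AT3G52720 (−1.47 and −1.07) and EXPA8 (−1.05 and −2.66). After jasmonate the calls of FBA5 and EXPA8 were lost in 2 and 6 of the 9 fits without 1 library. In opposite directions, 204 were higher after jasmonate and lower in lhp1 (261 for independent lists), led by AOC2 (3.68 and −2.40), ST2A (2.23 and −2.05) and MSRB6 (2.1 and −1.71). A further 329 were lower after jasmonate and higher in lhp1 (164 for independent lists), led by AT5G47330 (−2.91 and 2.1), AT5G22460 (−1.96 and 1.77) and AT2G18150 (−1.86 and 1.64). With mock WT replicate 2 left out these were −0.98 and 4.04, −0.96 and 2.77, and −0.998 (edgeR adjusted p = 0.0726) and 2.49. After jasmonate the calls of AT5G22460 and AT2G18150 were lost in 2 and 7 of the 9 fits without 1 library, and in lhp1 those of AT5G47330 and AT2G18150 in 5 and 2. Leaving out mock WT replicate 2 made the 4 counts 695, 340, 152 and 312, where independent lists give 272, 225, 295 and 207. The count of genes higher in both was 256 without mock WT replicate 3 and 237, 221 and 262 without mock lhp1 replicates 1 to 3. Genes lower in both numbered 100 and 86 without JA WT replicates 1 and 2 and 94, 81 and 79 without mock lhp1 replicates 1 to 3. Genes in opposite directions numbered 353 and 344 without JA WT replicates 1 and 2 and 275, 249 and 281 without mock lhp1 replicates 1 to 3, against 533. With total counts 284 genes were lower in both and 1109 in opposite directions. With only the 2 compared groups in each fit 280 were higher in both, 85 lower in both and 285 in opposite directions. Part of any excess may come from the shared controls, since 3 libraries cannot be divided into parts of at least 2.

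Across genes, which are not independent replicates, the covariance of the jasmonate and lhp1 log2 fold changes was −0.0403 (Pearson r = −0.115). In 40 simulations of unchanged groups with all libraries redrawn, its mean was 0.0208 (0.0190 to 0.0224), a difference of −0.0611. The mean simulated r was 0.490. Without mock WT replicate 2 the covariance was 0.0903 (simulated 0.0268, difference 0.0635) and r was 0.180 (simulated 0.592). The simulated r is no reference for r in the data. With no gene changed it reflects the shared controls alone, while changed genes add to the spread that r is scaled by. Without any 1 other library the covariance lay between −0.0467 and −0.0302. The sign also differed between settings with all 9 libraries kept. The covariance was 0.0642 with DESeq2 and 0.129 with no low-count filter, and both settings kept low-count genes. With the filter it was −0.0402 with RLE factors, −0.0252 with voom and −0.000144 with only the 2 compared groups in each fit.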

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

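The fits without mock WT replicate 2 are part of the planned series that leaves out each library, and the named genes, lists and overlaps given without it in the results were chosen after seeing the data. Counts moved with scaling and with single libraries, and lower genes outnumbered higher ones after jasmonate without mock WT replicate 3 (1998 against 1843). With total counts the balance turned in both comparisons, with 1217 genes higher and 3034 lower after jasmonate, 5045 higher and 1878 lower in lhp1, 284 lower in both comparisons and 1109 in opposite directions. The construction of this setting shows the cause, since it drops the composition factors. With only the 2 compared groups in each fit, 934 genes were lower after jasmonate, 280 higher in both, 85 lower in both and 285 in opposite directions, with 6 libraries in place of 9. Requiring an absolute log2 fold change of at least 1 left, by construction, 646 and 415 genes after jasmonate, 387 and 478 in lhp1, 50 higher in both, 12 lower in both, 53 opposite and 2482 between JA WT and mock lhp1, and excluded LHP1 itself at −0.91. With an estimated correlation 6 lists were called after jasmonate and 0 in lhp1, where fry called 7 and 1 list had an unadjusted p under 0.05. The covariance of the fold changes turned to 0.0642 with DESeq2 and to 0.129 with no low-count filter. Both settings kept low-count genes, while the filtered fits with RLE factors and voom stayed below 0 (−0.0402 and −0.0252). Which genes turned the sign was not tested. LHP1 after JA, not called in any direction, turned to −0.0103 with total counts and to −0.0431 without mock WT replicate 2 (range −0.0431 to 0.217 without 1 library). PDF1.2a in lhp1 turned to −0.12 without mock WT replicate 1, −0.07 without mock lhp1 replicate 1 and −0.03 without mock lhp1 replicate 3 (range −0.12 to 0.65).

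Leaving out each library in turn gave 1290 to 1843 genes higher and 1042 to 1998 lower after jasmonate, 1108 to 3295 higher and 2073 to 3571 lower in lhp1, 221 to 695 higher in both, 79 to 340 lower in both, 249 to 606 in opposite directions, 7785 to 10316 between JA WT and mock lhp1, a covariance of −0.0467 to 0.0903, LHP1 at −1.06 to −0.78, 10 to 13 lists after jasmonate and 6 to 9 in lhp1. In every such fit 1122 genes were higher and 816 lower after jasmonate, and 879 higher and 1791 lower in lhp1. Of 174 named gene results, 165 of them called, the side of the threshold and the direction were kept by 153 with DESeq2 (6 calls lost, 13 results without a DESeq2 adjusted p not compared), 163 with voom (10 lost), 171 with RLE factors (3 lost), 170 with no filter (4 lost), 167 with total counts (5 lost) and 139 with only the 2 groups (34 lost, 1 not compared), and 8 to 40 calls were lost without 1 library. With the replicate block the counts were 1880 and 1545 after jasmonate and 2628 and 3173 in lhp1, and 6 of the named calls were lost. Deviations of mock and jasmonate libraries with the same number correlated at 0.215, 0.0313 and 0.133, each best with its own number. Pairing of these 2 groups is thus not excluded, and the main model had no term for it. Deviations of mock WT and mock lhp1 correlated at −0.0766, −0.0106 and 0.0403, and those of JA WT and mock lhp1 at −0.0724, 0.0103 and 0.00994. Depth limits genes at a few counts, such as FT, SEP2 and MYB113, for which a bound or a wide interval is all these counts allow.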

Other observations

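The lists of iron, nitrate and carbonic anhydrase genes were chosen after their values were seen, as were the tests of the position of mock WT replicate 2, of that library's part in the covariance, and of green tissue. Iron uptake genes were lower after jasmonate in all 9 measured members (median log2 fold change −1.64; edgeR adjusted p below the threshold of 0.05; 8 without mock WT replicate 2). The call of BHLH100 was lost without any 1 of 6 libraries (JA WT replicates 2 and 3, mock WT replicates 1 and 2, mock lhp1 replicates 1 and 3) and that of BHLH101 without JA WT replicates 1 or 2. The ferric reductase gene FRO2 fell from 88.8 ± 7.35 to 17.4 ± 1.69 CPM (mean ± SD, n = 3; −2.35 ± 0.14, edgeR adjusted p = 4.76e-07), the iron transporter gene IRT1 from 157 ± 20.7 to 48.6 ± 8.87 CPM (−1.69 ± 0.16), their regulator FIT from 25.8 ± 2.25 to 12.3 ± 0.623 CPM (−1.06 ± 0.10) and the proton pump gene AHA2 from 1338 ± 183 to 764 ± 15.6 CPM (−0.81 ± 0.09). In lhp1, 2 of the 9 were lower (median −0.21), FIT (lost without mock lhp1 replicates 2 or 3) and CYP82C4 (lost without mock WT replicate 3 or mock lhp1 replicates 2 or 3). Of 5 nitrate genes, the transporter gene NRT2.1 fell after jasmonate and NRT1.1 rose (0.57, edgeR adjusted p = 0.0363; called in 2 of the 9 fits without 1 library, those without JA WT replicate 3 and without mock WT replicate 1), and no nitrate gene was called in lhp1 by edgeR.

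Of 4 ferritin genes, which encode iron storage proteins, 2 were lower and 1 higher in lhp1, and both listed carbonic anhydrase genes, whose products interconvert carbon dioxide and bicarbonate, were lower. These lists had no set test. The ferritin gene FER1 fell from 584 ± 387 to 88.2 ± 1.72 CPM (−2.73 ± 0.45, edgeR adjusted p = 0.00193) and FER4 from 30.3 ± 8.29 to 13.4 ± 0.303 CPM (−1.17), while the low FER2 rose (0.67, lost without JA WT replicate 2, mock WT replicates 1 or 3 or mock lhp1 replicates 1 or 2) and FER3 differed by −0.74 (edgeR adjusted p = 0.0505). CA1 fell from 1012 ± 399 to 226 ± 10.7 CPM (−2.16 ± 0.22) and CA2 from 745 ± 182 to 156 ± 3.91 CPM (−2.25 ± 0.15). After jasmonate neither the ferritins nor the carbonic anhydrases passed in the edgeR test, with FER1 at 0.85 (edgeR adjusted p = 0.214) and CA2 at 0.03 (−0.10 as the median of CA1 and CA2 with total counts). By replicate number FER1 was at 585, 1180 and 1394 CPM in JA WT against 228, 526 and 996 CPM in mock WT. FER1 and FER4 were higher in each same-numbered pair, and FER2 and FER3 were not. The main model had no term for pairing.

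Mock WT replicate 2 lay between the other mock WT libraries and mock lhp1. A library of lhp1 seedlings under a wrong label would lie at 0.8 or more of the way, and the median over the chosen genes was 0.4998. A mixture of the genotypes, whether of seedlings, RNA or reads, needs a single share for genes that rise and genes that fall, and the 2 median shares differed by 0.0291, so a mixed library is a candidate explanation. Seedlings of an intermediate or segregating genotype could give the same values, with 85.8% of genes at shares between 0.3 and 0.7, and cannot be told apart from a mixed tube because both predict shares around 1 value. The small gap between the 2 median shares rests on averaging mock WT replicates 1 and 3. Placed against each other over the lower genes, these lay at medians of −24.3% and 21.1%. Jasmonate-treated material was not visible in mock WT replicate 2, with a median share of 1.70% over 150 genes raised by jasmonate.

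The negative covariance between jasmonate and lhp1 fold changes may come from the same library. Without it the covariance was 0.0903, above the 0.0268 simulated for unchanged groups, and without any 1 other library it stayed below 0. Sampling error of shared controls adds covariance above 0 by arithmetic. The unchanged simulated groups (mean covariance 0.0208, none below 0) could hardly give another sign, so they were no test of it. A biological relation between jasmonate and LHP1 stays open. The sign also turned with DESeq2 and with no low-count filter, which both kept low-count genes.

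The lower photosynthesis genes in lhp1 were set against a smaller share of green tissue and against scaling. If less shoot tissue of unchanged cell makeup were the whole cause, shoot-borne stomatal lineage genes would fall alike. Without mock WT replicate 2, however, the photosynthesis median lay −0.93 from theirs, with quartiles of −1.55 to −1.26 against −0.54 to −0.39. A changed cell makeup of the shoot was not tested. A smaller shoot share as part of the fall stays open, since in the same fit root tip and endodermis markers had a median of 0.64 and root hair markers of 0.46. With total counts as the only scaling the median was −1.06 and 18 of 18 genes were lower, which argues against the composition factors. The lhp1 genotype itself stays open as an untested explanation.

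Genes at least 2-fold higher in lhp1 without mock WT replicate 2 lay next to each other more often than random placement gives, with 86 neighbouring pairs against 29.5, a ratio of 2.92 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). The ratio was 2.68 for genes lower in lhp1, 4.80 for genes higher and 2.95 for genes lower after jasmonate (permutation p = 0.0001, 0.0001 and 0.0005), so neighbours did not stand out in lhp1 alone, and tandem copies were not removed.

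The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real split called 3292 genes after jasmonate, 5344 in lhp1 and 9529 between JA WT and mock lhp1, and in each case 1 of the 10 splits reached that count, the highest other being 0 by edgeR, with at most 1846, 977 and 337 genes at an unadjusted p under 0.05. The camera test called 11 lists after jasmonate, reached by 4 of the 10 splits (highest other 13), and 8 in lhp1, reached by 2 of the 10 (highest other 9). Every other split has an unequal mix of both groups on each side, so part of the real difference remains in it. The counts of the other splits are therefore no chance level.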
